A study of Mus musculus with 15 samples.

How the data were processed

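CD4 T lymphocytes were sorted by flow cytometry from leukocytes of the small intestinal lamina propria of male mice, per the labels' protocols. Lysates went through SuperAmp, a commercial amplification used for small amounts of RNA, and 250 ng of the amplified cDNA was labelled with Cy3. Each of the 15 samples was hybridised to 1 one-colour Agilent array, and the groups were control chow, day 10 of a high-fat diet and day 30 of that diet, with 5 arrays each. Slide and scan, read from the deposited files, placed the 5 controls and day 10 replicates 1 to 3 on slide 1, and day 10 replicates 4 and 5 and the 5 day 30 arrays on slide 2. Nothing in the labels says that the 5 samples of a group came from separate mice, so the p-values measure only the spread between these samples, which may be technical.

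The scanner files hold linear intensity values made with Agilent Feature Extraction 10.7.3.1, protocol GE1_107_Sep09, on a grid annotated with build mm9, per the file headers. The processed intensity of a spot was background subtracted and spatially detrended within its array, with a surrogate value where the signal did not exceed background, and it was not scaled between arrays, per the file headers. The deposited value table holds log2 values whose 15 columns share 1 distribution, with a median of 5.51 and a maximum of 12.9 in each. Its order within an array matched that of the mean spot intensity (Spearman correlation of 1), its 23131 to 42649 values per array all came from spots well above background, and further steps the authors took to reach this log2 scale are not given in the sources used here. Probes were named with symbols from a RefSeq gene reference, matched on the transcript annotated for the probe or on a name shared with a matched probe. A probe without a match kept the name given with the array. No genome of build mm9 was used.

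Of 62975 spots per array, 59304 were not controls, for 55680 distinct probes and 34816 gene names. A symbol was found in this way for 29567 probes, and the names of the others include accessions. Outlier spots were left out, which left 45 probe values missing, and 1 damaged spot line was left out. No spot was saturated (0 on each array). The main values were log2 of the processed intensity minus the array's 75th percentile over all probes that were not controls. Spots of a probe were averaged, a gene was represented by its probe of highest mean signal, and a gene was tested if that probe was well above background on at least 5 of the 15 arrays. This kept 25997 genes and left out 8819 dim genes, and 11601 genes were well above background on all 15 arrays. Of the tested genes, 14688 carry a name that the naming rule allows, and 7336 had several probes that passed the filter. No pair of arrays looked like a repeat, since the smallest median absolute difference between 2 arrays was 0.80 log2 units against 1.07 for the median pair.

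Group means were fitted over all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided), so that the 3 groups share an estimate of the spread. Adjusted p-values are Benjamini-Hochberg values over the genes tested in a contrast, with a threshold of 0.05. Fold changes are differences of mean log2 values, later or dieted group minus the other. For a gene well above background on no array of a group, the fold is a lower bound written "at least N-fold". It is the bright group's mean against the dim group's mean of, on each array, the higher of the probe's own value and the lowest signal among probes well above background (between -5.13 and -2.87 over the arrays). No fold is given where this bound could not be formed. These bounds describe the group means of the processed signal without a slide block, not normexp values. They make no allowance for the spread between arrays.

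Before the data were examined, 34 gene lists were fixed. For the T cells themselves these were Th17, Th1, Th2, regulatory T cell, follicular helper T cell, T cell receptor and CD4 identity, naive and recirculating T cell, and gut homing, memory and residency. For cell states they were immediate early, heat shock, unfolded protein and amino acid stress response, proliferation, type I interferon response, NF-kB targets and inflammatory cytokines, microbial pattern sensing, TGF-beta signalling, cytokine signalling regulators, fatty acid oxidation and PPAR targets, cholesterol and fatty acid synthesis, glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, insulin and mTOR signalling, and apoptosis. Markers of other cells that a lamina propria preparation may hold covered CD8 T, NK and cytotoxic cell, innate lymphoid cell, B cell and plasma cell, macrophage and dendritic cell, granulocyte and mast cell, absorptive epithelium, secretory and antimicrobial epithelium, stroma, muscle and endothelium, pancreatic acinar cell, and red blood cell. The list cytosolic ribosomal proteins also named the translation elongation factor genes Eef1a1 and Eef2. Lists with at least 5 tested members (33 of the 34) were tested with camera at its preset correlation of 0.01, adjusted over the lists of a contrast.

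Named genes followed a rule fixed in advance. As no gene passed, it took the 16 nameable genes of smallest p in each contrast, the 3 members of smallest p in each called list, and 21 fixed T cell genes whatever their p. A member of smallest p within its list could serve as an example of it. Names that are accessions, clone names or coordinates were counted but not printed, and not every gene that the rule took is printed. List members were also adjusted over the list alone. This makes no allowance for the 33 lists, so some lists may hold a passing member by chance, and such members are examples rather than calls.

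The fits were tested on simulated data before they were run on the measured values. With 200 genes changed among 25986 in a data set of the measured noise, and 5 such sets per contrast, limma recovered 14.5% of 4-fold and 48.5% of 16-fold changes for day 10 against control, 17% and 58.5% for day 30 against control, and 16.5% and 47% for day 30 against day 10. Changes of 64-fold were recovered at 80.5%, 76% and 74% in the same order, and 2-fold changes at 0.5%, 3.5% and 1%. False calls per set averaged 1.4, 11.4 and 4.2 in that order. Of 50 simulated sets with no change between day 30 and control, camera at its preset correlation called at least 1 list in 31 and the cytosolic ribosomal protein list in 26, with a mean of 3.54 and a maximum of 13 lists a set. With an estimated correlation it called 0 lists in every one of these sets. Calls at the preset correlation are therefore descriptions here, not established shifts. Unchanged arrays were simulated as random normal combinations of the residual arrays. A first version that shuffled residuals within genes was dropped because residuals that sum to 0 over a group forced a correlation of 1 between the simulated changes.

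Alternatives fixed in advance were normexp background correction with an offset of 50, quantile normalization, median centring, the percentile over probes well above background on all arrays, the deposited table, both extremes of the dim-probe filter, the median of a gene's probes, slide as a fixed and as a random block, within-slide fits, the replicate number as a block, fits of only the compared groups, array weights, eBayes without trend, a 2-fold minimum, camera with an estimated correlation, fry, and leaving out each array in turn. The detection share as a covariate, leaving out the arrays of highest and lowest detection share, and raising values under the lowest signal well above background of their array to it were added after the data were seen. The number of arrays, at this noise between them, limits the precision. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the values and drew the plots.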

Results

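Gene expression was measured on 15 one-colour arrays in CD4 T cells sorted from the lamina propria of the small intestine, the tissue layer beneath the gut epithelium. Male mice had eaten control chow or had been on a high-fat diet for 10 or 30 days, and each of the 3 groups held 5 arrays. Per the series design text, the diet served to change the gut microbiota, and the title speaks of prediabetic and diabetic mice. The comparisons therefore ask how gut CD4 T cells differ at an early and a later point of the diet. The sample titles give no day for the controls, so whether they match day 10 or day 30 in time or age is not known. Time on the diet therefore cannot be told apart from time in the experiment or age in any of the 3 comparisons. The share of spots well above background was 63.8% ± 12.0 (SD, n = 5) in control, 58.5% ± 2.91 (SD, n = 5) at day 10 and 51.3% ± 5.48 (SD, n = 5) at day 30. Control replicate 1 had the highest share at 82.0%, and day 30 replicate 3 the lowest at 45.2%. Two-sided exact permutation tests gave p = 0.421 for day 10 against control, 0.0556 for day 30 against control and 0.0397 for day 30 against day 10. After Benjamini-Hochberg adjustment over the 3 comparisons these were 0.421, 0.0833 and 0.0833. Within slide 1 the share was 59.3% ± 3.26 (SD, n = 3) at day 10 against 63.8% ± 12.0 (SD, n = 5) in control (exact permutation p = 0.625). Within slide 2 it was 51.3% ± 5.48 (SD, n = 5) at day 30 against 57.3% ± 2.85 (SD, n = 2) at day 10 (exact permutation p = 0.238). No slide held both control and day 30 arrays. Over the tested genes, the correlation between 2 arrays lay between 0.627 and 0.819, and its median was 0.751 for arrays of the same group and 0.754 for arrays of different groups.

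**Figure D1:**
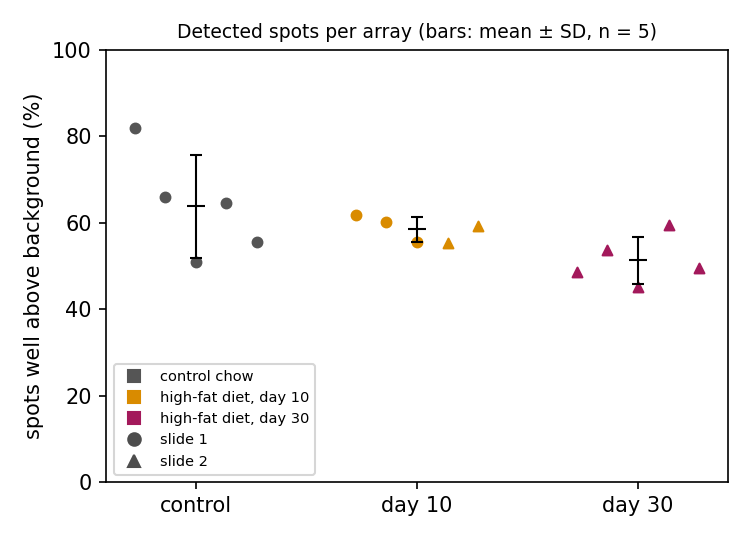
Share of spots well above background (percent) on each of the 15 arrays, by group and slide, with bars for the mean and SD (n = 5). The group means were 63.8% in control, 58.5% at day 10 and 51.3% at day 30, and control replicate 1 stood highest at 82.0%.

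The sorted cells carried the transcripts of CD4 T cells at high levels in all 3 groups. Cd4 averaged 3.31 ± 0.55 (SD, n = 5) in control, 3.68 ± 0.41 at day 10 and 4.12 ± 0.76 at day 30 on a log2 scale relative to the array's 75th percentile. These are values of its brightest probe, and its other probe had differences from control of the opposite sign, -0.07 at day 10 and -0.38 at day 30. Of the list T cell receptor and CD4 identity, 18 of the 20 members were well above background on all 15 arrays. Ctla4, an inhibitory receptor of activated and regulatory T cells, averaged 6.41 ± 1.16 in control and 6.42 ± 0.20 at day 10. Transcripts typical of other cells were also detected on all 15 arrays. They included the cytotoxic genes Gzma, Gzmb, Prf1 and Nkg7, the B-lineage genes Jchain, Pax5 and Cd22, the myeloid genes Csf1r and Apoe, the antigen-presentation genes Cd74 and H2-Ab1, and the epithelial genes Pigr and Krt18. Cd8a was well above background on 5 control, 4 day 10 and 3 day 30 arrays and Ms4a1 on 0. Reg3g, an antimicrobial lectin of the gut epithelium, was well above background on 3 control arrays, 1 day 10 array and 0 day 30 arrays. Of the fixed T cell genes, Il21 (well above background on 4 of 15 arrays) and Il4 (on 3) were too dim to be tested.

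Day 10 was compared with control to ask how these cells differed early on the diet. Among the T helper genes, the Th17 cytokine genes Il17f, Il22 and Il17a had lower means than in control, but they were not tested together as a set. Il17a had a log2 difference of -1.35 and was well above background on 2 day 10 and 4 control arrays. With values under the lowest signal well above background of their array raised to it, its difference was -0.88. Il17f averaged -3.77 ± 3.59 (SD, n = 5) at day 10 against 0.52 ± 2.14 in control, a log2 difference of -4.28 (SE 1.69). It was well above background on 5 control arrays but only 2 of 5 day 10 arrays, and the difference was -3.14 with values under the lowest signal well above background of their array raised to it. Il22 averaged -1.70 ± 0.72 against 1.03 ± 2.44, a log2 difference of -2.73 (SE 1.22). Over the alternatives these differences kept their sign, between -5.82 and -1.99 for Il17f and between -3.48 and -1.62 for Il22. Il23r, the receptor gene for a cytokine that sustains Th17 cells, had a log2 difference of only 0.09, and Ccr6 of 0.90. The 15 tested Th17 genes went both ways, 7 higher and 8 lower, with a median of -0.09 and a mean of -0.62. Camera did not call the list (adjusted p = 0.660; adjusted p = 0.951 with an estimated correlation). The master regulators of other subsets were close to control, with log2 differences of 0.20 for Tbx21, -0.51 for Gata3 and -0.32 for Foxp3. Of the 19 tested fixed genes, 7 were higher and 12 lower, 2 of them (Il17f and Il22) at an unadjusted p under 0.05, and 0 passed. A fit with slide as a block, which equals the comparison within slide 1, gave log2 differences of -3.64 for Il17f and -2.31 for Il22, neither of them at an unadjusted p under 0.05. Without control replicate 1 the Th17 median was -0.68 and the list was called lower (adjusted p = 0.00698, against 0.00542 to 0.987 over this list's alternatives at the preset correlation). Without control replicate 3 the median was 0.04.

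**Figure D2:**
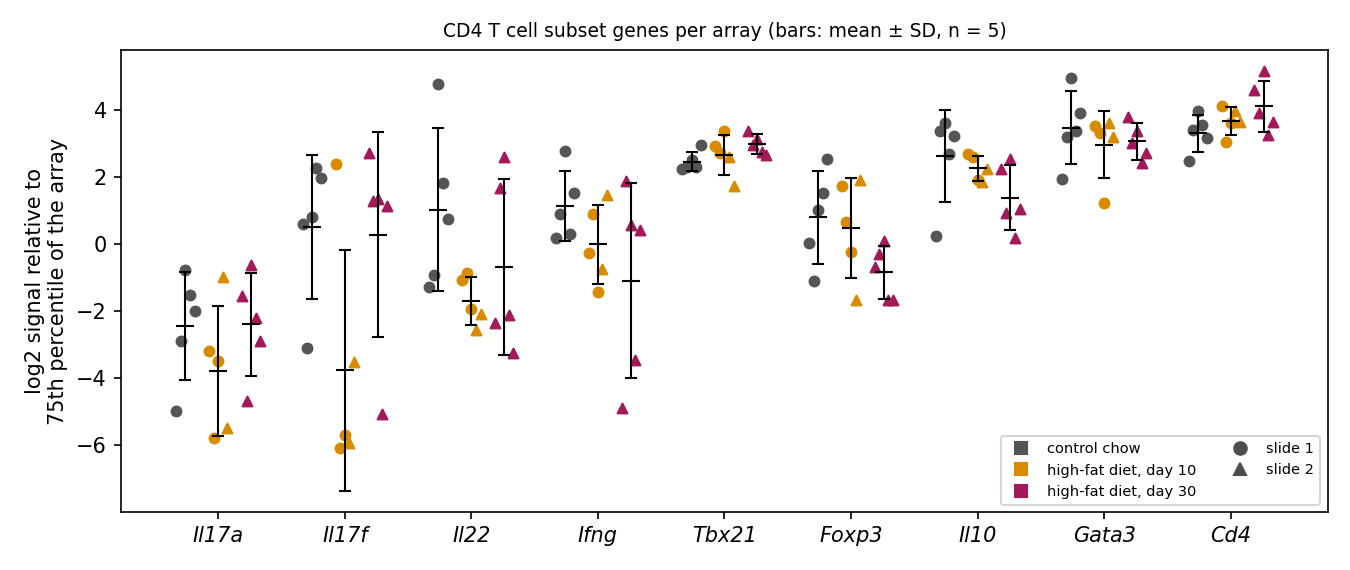
Log2 signal relative to the array's 75th percentile for 9 genes of CD4 T cell subsets, with each point an array and bars for the mean and SD (n = 5). The means of Il17f were 0.52 in control, -3.77 at day 10 and 0.29 at day 30, with points of all 3 groups overlapping.

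The genes of smallest p at day 10 were mostly lower. Of the 16 named by that rule, 3 were higher and 13 lower than in control, and their adjusted p lay between 0.704 and 0.970. Hspa1a, which encodes an inducible heat shock protein, averaged -4.10 ± 1.60 (SD, n = 5) against -0.55 ± 0.71 in control, a log2 difference of -3.55 (SE 0.78). Emc9, a member of the endoplasmic reticulum membrane protein complex, averaged -4.83 ± 1.51 against 0.05 ± 1.66, a difference of -4.88 (SE 0.90). Cpt2, a mitochondrial enzyme of fatty acid oxidation, had a difference of -3.98 (SE 0.97). The adhesion molecule Icam2 averaged 0.66 ± 0.78 against -3.07 ± 1.53, a difference of 3.73 (SE 0.82). The peroxisome gene Pex16 and the transcription factor gene Npas3 lay higher by 4.71 (SE 1.00) and 3.25 (SE 0.81). Ttc33 had a difference of -3.64 (SE 0.85). Of the genes lower at day 10, Hspa1a was well above background on 3 of 5 day 10 arrays, Emc9 on 2, Cpt2 on 1 and Ttc33 on 1, and of those higher, Pex16 on 2 of 5 control arrays, Npas3 on 3 and Icam2 on 4. With values raised to the lowest signal well above background the differences were -2.88 for Hspa1a, -3.80 for Emc9, -2.71 for Cpt2, -2.19 for Ttc33 and 3.72 for Pex16. For genes well above background on no day 10 array only a lower bound of the fold holds. Ckap2l, a gene of the mitotic spindle, was at least 19.8-fold lower, Crybg3 at least 11.3-fold, Enc1 at least 9.22-fold and Olfr1201 at least 9.07-fold. Lower in the same way were Ndufaf2 at least 8.66-fold, Taco1 at least 8.47-fold, Rufy3 at least 5.45-fold and Gemin8 at least 4.76-fold. With normexp the differences of these genes were all smaller than their bounds, from -3.09 for Ckap2l to -1.16 for Gemin8. The brightest probe of Gstm3 was well above background on 4 control arrays and 0 day 10 arrays, while another of its probes had the opposite sign. Blocking on slide gave differences of -3.20 for Hspa1a, -4.67 for Emc9, -4.32 for Cpt2, 3.59 for Icam2 and 3.93 for Pex16. By limma, 0 of 25997 genes had an adjusted p under 0.05 (smallest 0.704). At an unadjusted p under 0.05 there were 673, 231 higher and 442 lower (396 and 395 with quantile normalization), where chance gives 1299.85. Groups did not overlap at all for 109 genes, 0.419% against 0.794% by chance.

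Cytosolic ribosomal proteins were the 1 list of 33 that camera called at day 10, as higher. Of its 48 genes, 45 lay above control and 3 below, with a median log2 difference of 0.28 (adjusted p = 4.47e-06; adjusted p = 0.951 with an estimated correlation). Rps9 averaged 7.01 ± 0.56 (SD, n = 5) against 6.37 ± 0.63 in control, a difference of 0.64 (SE 0.30), Rplp1 had 1.06 (SE 0.55) and Rps15 0.63 (SE 0.35). The median was 0.18 with slide as a block (adjusted p = 0.186), the same within slide 1 (adjusted p = 0.203), -0.05 with the detection share as a covariate (adjusted p = 0.676) and 0.01 without control replicate 1 (adjusted p = 0.979), where the alternatives at the preset correlation ranged from 2.81e-15 to 0.979. Without that array camera called 5 lists, all lower (Th17, regulatory T cell, immediate early, heat shock, and gut homing, memory and residency). Without control replicate 3 it called 4 lists, all higher, with a median of 0.51 for cytosolic ribosomal proteins. Markers of cytotoxic cells lay higher without a call, 12 of 15 genes in CD8 T, NK and cytotoxic cell with a median of 0.61 (adjusted p = 0.189), which turned to -0.16 in the deposited table. Adjusted over the list alone, with no allowance for the 33 lists, 5 members of 4 lists passed. They were Hspa1a in heat shock (0.00412), and Cpt2 (0.0219) and Ppara (0.0305; log2 difference -2.26) in fatty acid oxidation and PPAR targets. The others were H2-Aa (0.0268; log2 difference -5.17, SE 1.33; well above background on 1 of 5 day 10 arrays, and -4.15 with values raised in the same way as for Il17f) in macrophage and dendritic cell and Actn1 (0.0397; log2 difference -5.20, or -4.09 with values so raised; on 2 of 5) in naive and recirculating T cell. Camera with an estimated correlation called 0 lists (smallest adjusted p 0.637), and so did fry (0.976).

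Day 30 was compared with control to ask how these cells differed after a longer time on the diet. Genes of the protein synthesis machinery lay higher together, except in the deposited table and with the detection share as a covariate. All 48 tested genes of the list cytosolic ribosomal proteins were above control, with a median log2 difference of 0.64 (-0.05 in the deposited table). Of them, 16 had an unadjusted p under 0.05. Rps9 averaged 7.39 ± 0.21 (SD, n = 5) against 6.37 ± 0.63 in control, a difference of 1.02 (SE 0.30), and Rps15 had 1.00 (SE 0.35). Camera called the list higher (adjusted p = 1.99e-19; adjusted p = 0.716 with an estimated correlation). In the deposited table all genes had a median of -0.25, and relative to them the list was still called higher (adjusted p = 0.00958). The list's median was 0.35 with slide as a block (adjusted p = 0.0591) and -0.08 with the detection share as a covariate (adjusted p = 0.145). For cytosolic ribosomal proteins it was 0.32 without control replicate 1 (adjusted p = 1.25e-08) and 0.22 without that array and day 30 replicate 3 (adjusted p = 3.1e-05), where the alternatives at the preset correlation ranged from 4.22e-27 to 0.145. Within groups, the list's mean over the 15 arrays was lower where more spots were detected, with Pearson r = -0.895 (permutation p = 0.00064) and Spearman rho = -0.643 (permutation p = 0.0217). Without the 2 arrays farthest from the median share (control replicates 1 and 3) r was -0.653, and it was -0.883 within slide 1 (8 arrays) and -0.962 within slide 2 (7 arrays). Pooled over groups, r was -0.927 (permutation p = 2e-05; 4e-05 after Benjamini-Hochberg adjustment over both relations).

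**Figure D3:**
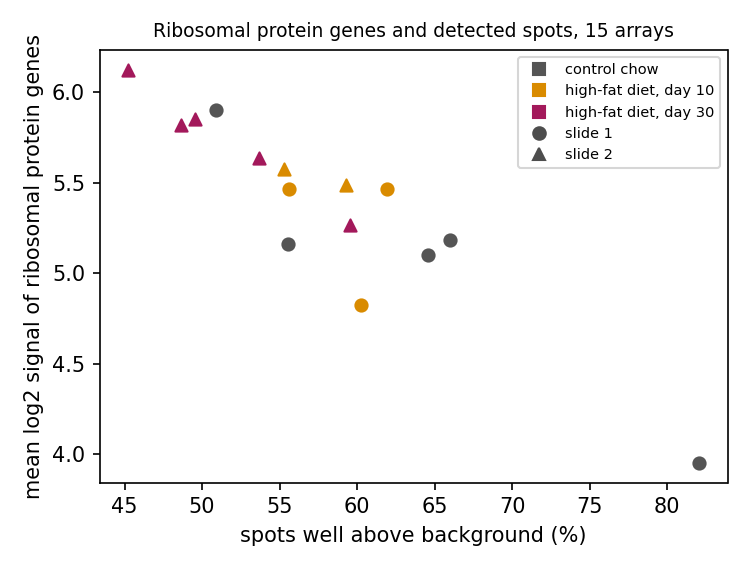
Mean log2 signal of the ribosomal protein genes (relative to the array's 75th percentile) against the share of spots well above background (percent), for 15 arrays coloured by group, with a symbol for each slide. Arrays with fewer detected spots had higher values (pooled Pearson r = -0.927), and control replicate 1, at 82.0% of spots, had the lowest.

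Camera also called 2 other lists higher at day 30. In T cell receptor and CD4 identity, 17 of 20 genes lay above control, with a median of 0.33 (adjusted p = 0.0279; adjusted p = 0.991 with an estimated correlation). Thy1 averaged 5.40 ± 0.27 (SD, n = 5) against 4.48 ± 0.61, a difference of 0.91 (SE 0.32), Cd5, a negative regulator of receptor signalling, had 1.49 (SE 0.60), the adaptor gene Lat 0.76 (SE 0.37) and Cd4 0.81 (SE 0.39; -0.38 for its other probe). In oxidative phosphorylation, 28 of 37 genes lay above control, with a median of 0.42 (adjusted p = 0.0234; adjusted p = 0.991 with an estimated correlation). Its members of smallest p were Atp5o at 2.71 (SE 1.12), Ndufs1 at 1.01 (SE 0.43) and Ndufa2 at 0.97 (SE 0.41). Neither call held with slide as a block. The medians were then 0.09 (adjusted p = 0.814) for T cell receptor and CD4 identity and -0.06 (adjusted p = 0.863) for oxidative phosphorylation. Over their alternatives at the preset correlation the adjusted p ranged from 0.000302 to 0.848 and from 0.000206 to 0.863. In the deposited table the medians turned to -0.28 and -0.16, and the T cell median was -0.06 with the percentile over detected probes. The first list was called lower with the detection share as a covariate (median -0.48, adjusted p = 0.0392). Within groups, both lists' means were lower where more spots were detected, with Pearson r of -0.878 for T cell receptor and CD4 identity (permutation p = 0.00163, 0.0139 adjusted over 34 lists) and -0.722 for oxidative phosphorylation (permutation p = 0.00963, 0.0364 adjusted). The T cell call ended without control replicate 1 (median -0.01, adjusted p = 0.757), control replicate 2 (0.49, 0.0550), day 30 replicate 2 (0.58, 0.0532), day 30 replicate 3 (0.26, 0.123) and day 30 replicate 5 (0.27, 0.249). That of oxidative phosphorylation ended without control replicate 1 (0.26, 0.478), control replicate 2 (0.41, 0.0672) and day 30 replicate 5 (0.40, 0.214). Both calls also ended with values under the lowest signal well above background raised to it (adjusted p = 0.131 and 0.128), where the medians were unchanged at 0.33 and 0.42. Medians moved further without control replicate 3 (0.75 for T cell receptor and CD4 identity and 0.65 for oxidative phosphorylation), without day 30 replicate 1 (0.53 for the first) and without control replicate 5 (0.68 for the second). The number of called lists was 1 without control replicate 2 and without day 30 replicate 5, 5 without control replicate 3 and without control replicate 5, and 6 without day 30 replicate 4. Camera with an estimated correlation called 0 lists (smallest adjusted p 0.716), and fry 0 (0.591).

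**Figure D4:**
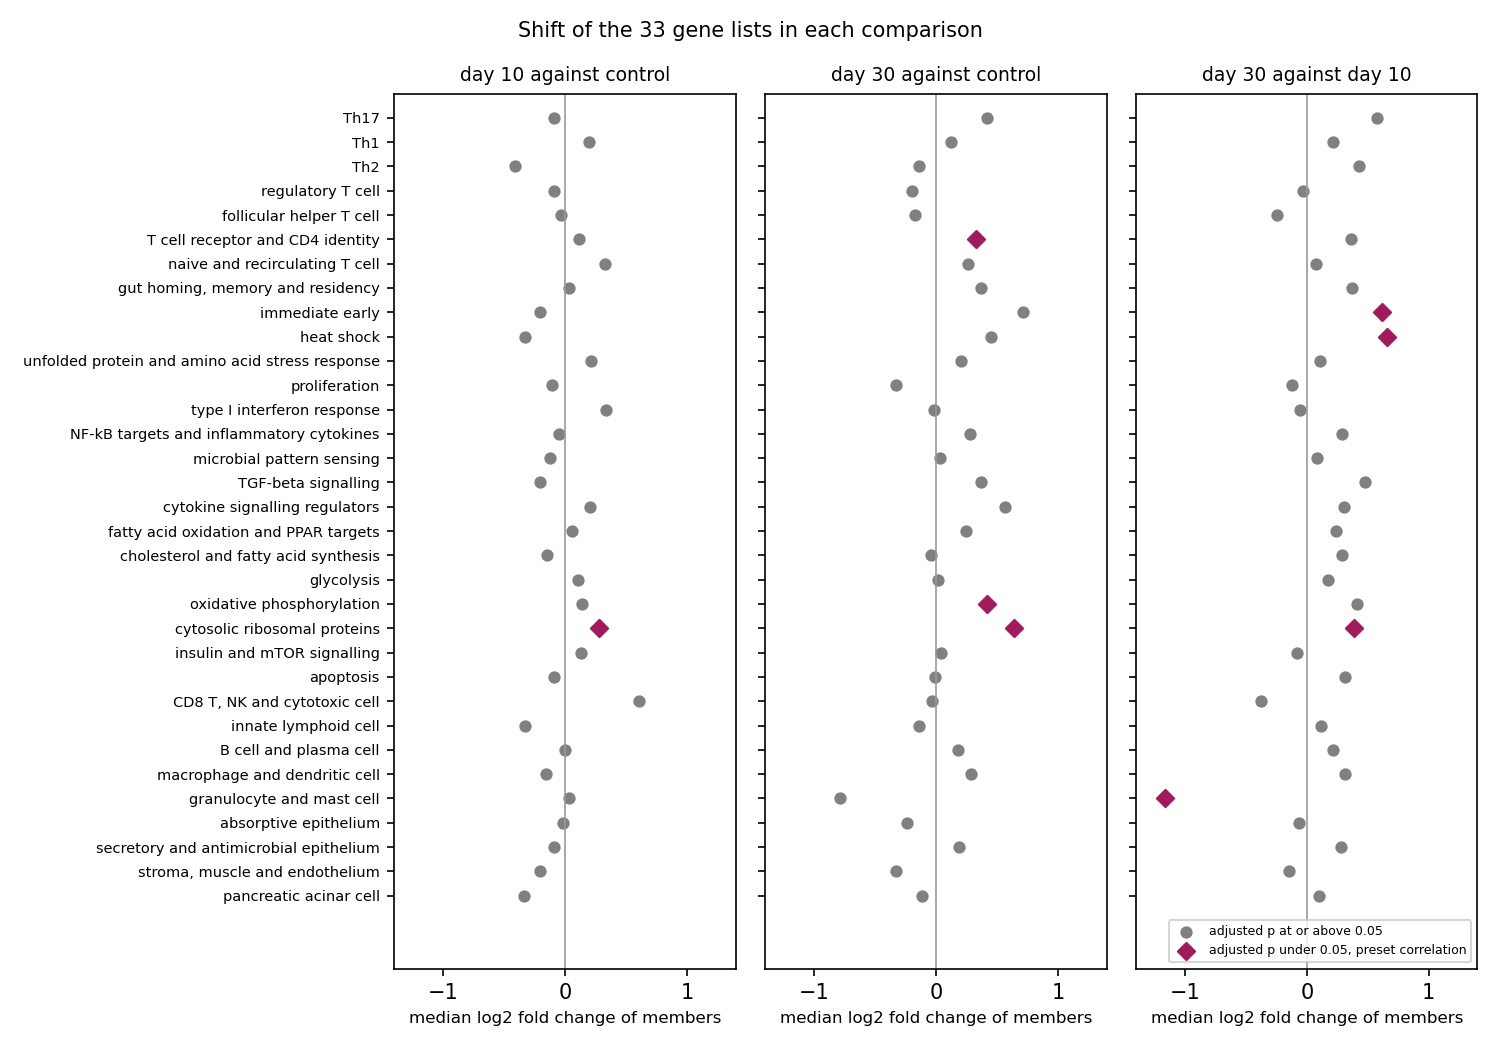
Median log2 fold change over the tested members of each of 33 gene lists in the 3 comparisons, with diamonds for lists at an adjusted p under 0.05 by camera at its preset correlation and circles for the others. Cytosolic ribosomal proteins had medians of 0.28, 0.64 and 0.38, and 0 lists were called with an estimated correlation.

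At day 30 the T cell subset genes showed no common direction. The gene of the regulatory T cell master regulator, Foxp3, averaged -0.84 ± 0.80 (SD, n = 5) against 0.80 ± 1.39 in control, a log2 difference of -1.65 (SE 0.78) with 5 of 5 day 30 arrays below the control mean. The anti-inflammatory cytokine gene Il10 averaged 1.39 ± 0.97 against 2.64 ± 1.37, a difference of -1.25 (SE 0.61). Both kept their sign over the alternatives, between -2.16 and -1.05 for Foxp3 and between -2.52 and -0.90 for Il10. Ifng, the main Th1 cytokine gene, averaged -1.09 ± 2.91 against 1.14 ± 1.06, a difference of -2.23 (SE 1.11), while Tbx21, the Th1 master regulator, had 0.52 (2.98 ± 0.29 against 2.46 ± 0.29). The Th17 genes Il17a, Il17f and Il22 had differences of 0.04, -0.23 and -1.72, and Gata3 had -0.41. The 19 tested regulatory T cell genes had a median of -0.20 (adjusted p = 0.400), and the 14 Th1 genes a median of 0.12 and a mean of -0.11 (adjusted p = 0.805). Over 26 alternatives at the preset correlation the regulatory T cell median ran from -1.38 to 0.15, and 5 called the list. Within groups, this list's mean was lower where more spots were detected (Pearson r = -0.834, permutation p = 0.00847, 0.0360 adjusted over 34 lists). The 15 Th17 genes had a median of 0.42 and a mean of -0.02, with camera's direction up (adjusted p = 0.989). Of the 19 tested fixed genes, 12 were higher and 7 lower, 1 (Foxp3) at an unadjusted p under 0.05, and 0 passed. Blocked on slide, the differences were -1.05 for Foxp3, -0.90 for Il10, -2.85 for Ifng, 1.36 for Tbx21 and 1.37 for Il17f, the last with the opposite sign, and at an unadjusted p under 0.05 Foxp3 was then lost and Tbx21 gained. The Th17 median was -0.09 without control replicate 1 and -0.06 without day 30 replicate 3.

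Among the single genes of smallest p at day 30, 5 of 16 were higher and 11 lower than in control. Csnk2a2, a catalytic subunit gene of a casein kinase, averaged 2.82 ± 0.25 (SD, n = 5) against 0.36 ± 0.84, a difference of 2.45 (SE 0.45), and Cd200r2 2.15 ± 0.56 against -0.60 ± 1.02 (2.75, SE 0.53). Rab5if averaged 3.00 ± 1.14 against -0.42 ± 0.63 (3.42, SE 0.70), Slc9a3r1 2.84 ± 0.55 against 0.43 ± 1.07 (2.41, SE 0.57) and Ubxn1 2.00 ± 0.59 against 0.03 ± 0.82 (1.98, SE 0.47). The phosphatase gene Dusp14 averaged -3.61 ± 1.39 against 1.74 ± 1.35, a difference of -5.34 (SE 1.05). Mrps21, which encodes a mitochondrial ribosomal protein, had a difference of -4.75 (SE 0.94), Nol9 of -4.27 (SE 0.86; -0.24 for its other probe), As3mt of -5.07 (SE 1.20) and Gemin8 of -3.40. Dusp14 and Nol9 were each well above background on 2 of 5 day 30 arrays, and Mrps21, As3mt and Gemin8 on 1. With values raised to the lowest signal well above background the differences were -4.88 for Dusp14, -3.22 for Mrps21, -4.20 for Nol9, -3.51 for As3mt and -1.64 for Gemin8. The brightest probe of Cage1 was well above background on 4 control arrays and 0 day 30 arrays. Emc9, Ufsp2, Asxl1, Suclg2 and Cenpv were well above background on no day 30 array and were at least 12.2-fold, 9.23-fold, 8.09-fold, 7.70-fold and 5.29-fold lower. Of the list macrophage and dendritic cell, Cd74 had a difference of 2.55 (SE 0.64), H2-Ab1 of 1.4 and H2-Aa of -4.52 (SE 1.33; well above background on 2 of 5 day 30 arrays, and -3.65 with values so raised). The slide-blocked differences were 3.24 for Csnk2a2, 2.39 for Cd200r2, 5.91 for Rab5if, 1.00 for Slc9a3r1, -2.07 for Dusp14, -0.65 for As3mt, 3.83 for Cd74 and -3.53 for H2-Aa. They were -7.58 for Mrps21, -2.58 for Nol9, -1.97 for Gemin8 and 2.22 for Ubxn1. Among the genes with a bound they were -4.83 for Emc9, -2.91 for Ufsp2, -6.80 for Asxl1, -4.06 for Cenpv and -2.17 for Suclg2, the value for Ufsp2 and that for Suclg2 being smaller folds than their bounds. Of these genes, Slc9a3r1, Dusp14, As3mt, H2-Aa, Nol9, Gemin8, Ufsp2 and Suclg2 were then not at an unadjusted p under 0.05. With normexp the differences of the genes with a bound were all smaller than the bound, from -2.33 for Emc9 to -0.99 for Cenpv. A bound therefore describes only the group means of the processed signal without a slide block. By limma, 0 of 25997 genes passed (smallest adjusted p 0.367), and 1337 had an unadjusted p under 0.05, 643 higher and 694 lower, where chance gives 1299.85. Other scalings moved that split to 728 and 366 (normexp), 247 and 1234 (percentile over detected probes) and 195 and 1589 (deposited table). With values under the lowest signal well above background raised to it the split was 825 and 432, and without control replicate 3 it was 1364 and 902. Groups did not overlap for 157 genes, 0.604% against 0.794% by chance. Adjusted over the list alone, with no allowance for the 33 lists, 6 members of 5 lists passed. They were Rptor (0.0146; log2 difference 3.58) in insulin and mTOR signalling, and Cd74 (0.0228) and H2-Aa (0.0370) in macrophage and dendritic cell. The others were Ccr7 (0.0277; 2.75, or 2.51 with values so raised; well above background on 1 of 5 control arrays) in naive and recirculating T cell, Hspa1a (0.0300; -2.81; on 2 of 5 day 30 arrays) in heat shock and Mvk (0.0360; 1.64) in cholesterol and fatty acid synthesis. Blocked on slide, Hspa1a had -1.93 and Mvk 0.80, neither at an unadjusted p under 0.05. Rptor then had 3.92 and Ccr7 3.81, both under it. A fit with slide as a fixed block called 1 gene, Vkorc1l1 (log2 difference -12.70, adjusted p = 0.00864, against -5.60 and 0.883 without the block; well above background on 1 of 5 day 30 arrays), which the naming rule did not take. With slide as a random block there were 7 genes (Emc9, Csnk2a2, Nol9, Cd200r2, Dusp14 and 2 without a gene name; adjusted p 0.0312 to 0.0394, and up to 1.00 for Emc9 over the other alternatives). The consensus correlation there was -0.0635, a negative value, which makes such p-values too small.

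Day 30 was compared with day 10 to ask how the cells differed between the early and the later diet. Genes of acute activation and of protein folding lay higher at day 30. In immediate early, 18 of 19 genes lay above day 10, with a median of 0.61 (adjusted p = 0.00176; adjusted p = 0.847 with an estimated correlation). Among them were Atf3 at 3.43 (SE 1.29; 2.97 ± 1.22 against -0.46 ± 3.34, SD, n = 5; 1.99 without day 10 replicate 4), Dusp2 at 2.12 (SE 1.15; -0.41 in the deposited table) and Egr1 at 1.29 (SE 0.62). In heat shock, 11 of 12 genes lay above day 10, with a median of 0.66 (adjusted p = 0.00777; adjusted p = 0.847 with an estimated correlation). They included the chaperone genes Hspe1 at 1.25 (SE 0.56), Hsph1 at 1.16 (SE 0.54) and Hspa8 at 0.59 (SE 0.34). In cytosolic ribosomal proteins, 47 of 48 genes lay above day 10, with a median of 0.38 that turned to -0.08 in the deposited table (adjusted p = 1.15e-06; adjusted p = 0.847 with an estimated correlation). Without day 10 replicate 2 the median of cytosolic ribosomal proteins was 0.27 (adjusted p = 0.0103). Examples were Rps19 at 0.98 (SE 0.54) and Rpl18 at 0.60 (SE 0.37). Granulocyte and mast cell was called lower, with 8 of 11 genes below day 10 and a median of -1.17 (adjusted p = 0.0202; adjusted p = 0.325 with an estimated correlation). With values under the lowest signal well above background of their array raised to it, granulocyte and mast cell had a median of only -0.06 and was not called (adjusted p = 0.348), so the size of this difference rests on values under background. Its genes of smallest p were the mast cell receptor gene Kit at -2.47 (SE 1.07; -2.03 with values so raised; well above background on 4 day 10 and 3 day 30 arrays), the eosinophil lectin gene Siglecf at -2.11 (SE 1.06; -1.39; on 4 and 1), and Mpo, well above background on 2 day 10 arrays and 0 day 30 arrays, whose difference turned to 0.25 with values so raised. Of the genes in granulocyte and mast cell, on average 53.0% were well above background in control, 49.0% at day 10 and 33% at day 30. Over all spots the shares were 63.8%, 58.5% and 51.3%, so a drop in detection is not particular to this list.

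With slide as a block, or within slide 2 (2 day 10 and 5 day 30 arrays), none of these 4 lists was called. The blocked medians were 0.51 for immediate early, 0.60 for heat shock, 0.20 for cytosolic ribosomal proteins and -0.27 for granulocyte and mast cell, each with an adjusted p of 0.297. Within slide 2 the adjusted p were 0.307, 0.188, 0.167 and 0.296. Over their alternatives at the preset correlation the adjusted p ranged from 3.19e-05 to 0.839 for immediate early, 3.19e-05 to 0.770 for heat shock, 7.28e-10 to 0.748 for cytosolic ribosomal proteins and 0.00853 to 0.348 for granulocyte and mast cell. Within groups, the means of immediate early and heat shock were also lower where more spots were detected, with Pearson r of -0.825 (permutation p = 0.00394, 0.0208 adjusted over 34 lists) and -0.833 (permutation p = 0.00068, 0.0116 adjusted). For granulocyte and mast cell r was 0.401 (permutation p = 0.10, 0.148 adjusted). The median of immediate early was 0.41 without day 10 replicate 2 and 0.94 without day 10 replicate 4. Heat shock was not called without day 10 replicate 2 (median 0.50, adjusted p = 0.0866) or day 30 replicate 5 (0.58, 0.0743). The granulocyte and mast cell call ended without day 10 replicate 2 (-0.82, 0.105), day 30 replicate 2 (-1.42, 0.0513), day 30 replicate 4 (-0.98, 0.0502) and day 30 replicate 5 (-0.96, 0.105). The number of called lists was 2 without day 10 replicate 2 and without day 30 replicate 5, and 7 without day 30 replicate 1. Camera with an estimated correlation called 0 lists (smallest adjusted p 0.325), and fry 0 (0.266).

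The Th17 cytokine gene Il17f lay higher at day 30 than at day 10, with means of 0.29 ± 3.06 and -3.77 ± 3.59 (SD, n = 5) and a difference of 4.05 (SE 1.69). It was well above background on 4 of 5 day 30 and 2 of 5 day 10 arrays, and the difference was 3.14 with values raised to the lowest signal well above background. Il17a and Il22 had differences of 1.39 (0.91 with values so raised) and 1.01. The Th17 list as a whole had 12 genes above and 3 below, a median of 0.58 and no call (adjusted p = 0.249; adjusted p = 0.847 with an estimated correlation). Foxp3, Il10 and Ifng had differences of -1.32, -0.87 and -1.08. Of the 19 tested fixed genes, 16 were higher and 3 lower, 1 (Il17f) at an unadjusted p under 0.05, and 0 passed. Among the 16 genes of smallest p, 3 were higher and 13 lower. Pdcd1, which encodes the inhibitory receptor PD-1, averaged -1.01 ± 2.58 against 3.12 ± 0.81, a difference of -4.13 (SE 0.95). The tight junction gene Cldn4 averaged -1.96 ± 0.41 against 0.33 ± 0.75 (-2.28, SE 0.50). Npas3, which lay above control at day 10, averaged -4.64 ± 1.33 against -0.57 ± 0.58 (-4.06, SE 0.81). Farsb, Psmd5, Urb1 and Mrps21 had differences of -4.22, -4.82, -5.10 and -4.10. Of these genes, Pdcd1 was well above background on 4 of 5 day 30 arrays, Farsb and Psmd5 on 2, and Npas3, Urb1 and Mrps21 on 1. With values so raised the differences were -3.81 for Pdcd1, -2.78 for Npas3, -3.18 for Farsb, -3.86 for Psmd5, -3.62 for Urb1 and -2.58 for Mrps21. The brightest probe of Cage1 was well above background on 4 day 10 arrays and 0 day 30 arrays, and that of Pcgf2 on 0 and 4. The translation initiation gene Eif2s2 averaged 2.73 ± 0.84 against -0.15 ± 1.09 (2.88, SE 0.67; 0.32 for its other probe). Exoc2 was at least 17.2-fold higher at day 30. Olfr575, Ryr3, Cenpv, Tmlhe and Ralgps2 were at least 13.9-fold, 6.44-fold, 5.82-fold, 3.86-fold and 3.23-fold lower. With normexp these differences were all smaller than their bounds, from -2.58 for Olfr575 to -0.92 for Tmlhe, and 2.45 for Exoc2. Slide-blocked differences were 5.01 for Il17f, -4.38 for Pdcd1, -2.29 for Cldn4, -4.23 for Npas3 and 2.51 for Eif2s2. By limma, 0 of 25997 genes passed (smallest adjusted p 0.432), and 1067 had an unadjusted p under 0.05, 472 higher and 595 lower. Other scalings moved that split to 597 and 348 (normexp), 593 and 499 (median centring), 243 and 862 (percentile over detected probes) and 205 and 596 (deposited table), and values raised to the lowest signal well above background to 616 and 385. Groups did not overlap for 148 genes, 0.569% against 0.794% by chance. Adjusted over the list alone, with no allowance for the 33 lists, 3 members passed. They were Pdcd1 (0.00491) in follicular helper T cell, and Ccnb2 and Mcm6 (each 0.0483) in proliferation. Ccnb2 and Mcm6 were well above background on 0 and 2 of 5 day 30 arrays. Without day 10 replicate 4, 2 genes passed over all genes, Suclg2 (well above background on 0 day 30 arrays) and As3mt (-5.55), each with an adjusted p of 0.0287, against 0.958 and 0.999 with all arrays.

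The 2 diet comparisons shared their control arrays, so their fold changes were compared with unchanged simulated groups. Across 25986 genes, which are not independent replicates, the changes at day 10 and day 30 had a correlation of 0.455 and a covariance of 0.432. Unchanged groups against shared simulated controls gave a correlation of 0.50 (SD 0.229) and a covariance of 0.534 (SD 0.361) over 100 simulations. With the controls split so that each comparison used its own, the correlation was -0.0466 on average over 20 splits, between -0.225 and 0.0473, and the covariance was -0.0811. At an unadjusted p under 0.05, 187 genes appeared in both comparisons, among them Emc9, Gemin8 and Hspa1a, all 3 lower at both days. The unchanged simulated groups gave a median of 147 such genes, and at least 187 in 42 of the 100 simulations.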

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

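The counts over other splits of the arrays and the tests of the detection share, the slide, the share of Th17 cells and the share of antigen-presenting cells were chosen only after the results they test were seen.

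The changes at day 30 and at day 10, each against the same controls, differed by camera at its preset correlation for immediate early (adjusted p = 0.00176), heat shock (adjusted p = 0.00777), cytosolic ribosomal proteins (adjusted p = 1.15e-06) and granulocyte and mast cell (adjusted p = 0.0202). None of these held with an estimated correlation (adjusted p 0.847, 0.847, 0.847 and 0.325), and that of granulocyte and mast cell was also lost with values under background raised to the lowest signal well above it (median -0.06, adjusted p = 0.348). Single arrays stood apart by Dixon's test, which sets the gap to the nearest array of the group against the group's range, in 11 of 228 sets of 5 arrays, where chance at 1 in 20 gives 11.4. In control, replicate 1 was lowest for Cd3e (0.835), Hspa8 (0.777) and Il10 (0.730). At day 10, replicate 2 was lowest for the mean of cytosolic ribosomal proteins (0.853) and of glycolysis (0.740), and replicate 3 for Gata3 (0.825) and the mean of type I interferon response (0.726). At day 30, replicate 4 was lowest for Il17f (0.794) and the mean of heat shock (0.720), and replicate 2 for Ndufs1 (0.753) and the mean of absorptive epithelium (0.754).

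The list of cytosolic ribosomal proteins was higher at day 30 than in control by a median of 0.64, and 13 of 100 splits of the 10 arrays gave a median as large (highest other 0.95), so chance was not excluded. A change of ribosomal protein transcripts with the diet may lie behind it, but the share of detected spots could account for it as well. Within groups r was -0.895, and with that share as a covariate the median was -0.08. The list is bright, and scaling to a percentile of the array may itself tie bright lists to that share, which was not tested. Whether the share itself is only technical was not tested. Slide stays open, since a median of 0.35 was left with slide as a block and no slide held both control and day 30. That bright genes shift together also stays open. The list lay at percentile 99.97 of 10000 random lists matched on brightness, a value set beforehand to argue against it, but that bound was wrong because the list's genes move together and random lists do not, so the test was void.

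Il17f and Il22 lay 4.28 and 2.73 log2 units below control at day 10 (log2 differences -4.28 and -2.73). A loss of Th17 cells as large as the smaller of these falls was argued against for the sorted cells. The other 13 tested members of the Th17 list had a median difference of 0.060 (SD 0.74) against -2.73. Some of these members are expressed by other T cells as well, and a smaller loss was not tested. Random loss of rare transcripts between arrays could account for part of these falls. Of 1000 genes of like brightness, 1.3% for Il17f and 1.2% for Il22 had a change of at least 2.73 log2 units, the smaller fall. Neither share was under the 1% nor over the 5% set beforehand. These were the 2 of 19 tested fixed genes at an unadjusted p under 0.05, and the shares do not allow for that choice. Lower transcription of these cytokine genes within Th17 cells on the diet remains open and was not tested.

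H2-Aa lay below control at day 30 by a log2 difference of -4.52, while Cd74 had 2.55. A loss of antigen-presenting cells as large as the fall of H2-Aa was argued against for the sorted samples. The other 31 tested members of the lists for macrophage and dendritic cell and for B cell and plasma cell had a median of 0.28 (SD 1.14). Members near background could not have fallen as far, and a smaller loss of these cells was not tested. Loss of a rare transcript stays open: 0.1% of genes of like brightness had a change as large, under the 1% set beforehand, but that bound was wrong for a gene singled out after its value was seen from 616 tested genes of the lists, among which such a share gives 0.616 genes. A change of H2-Aa in the cells with the diet is a further candidate explanation and was not tested.

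Over 100 splits of the arrays into groups of 5, chance was not excluded for the counts of genes at an unadjusted p under 0.05 and of called lists or for the size of the Th17 median. For genes at an adjusted p under 0.05 the real count was 0 in each comparison, which every split reaches, so this test could not have come out otherwise and decides nothing. For day 10 against control, 100 splits gave at least the real 0 genes at an adjusted p under 0.05 (highest other 6), 92 gave at least 673 genes at an unadjusted p under 0.05 (highest other 3535), 81 at least 1 called list (highest other 20) and 87 a Th17 median at least 0.09 from 0 (highest other 1.49). For day 30 against control these were 100 splits (real 0, highest other 9), 52 (real 1335, highest other 3733), 61 (real 3, highest other 22) and 50 (real 0.42, highest other 1.36), and here the real split is also the split by slide. For day 30 against day 10 they were 100 splits (real 0, highest other 3), 70 (real 1065, highest other 2133), 14 (real 4, highest other 12) and 9 (real 0.58, highest other 1.10). These counts used the 25986 genes without a missing value. Splits with several times the real number of genes or lists may reflect a structure among the samples other than their groups, or correlation among genes, since unchanged simulated sets gave up to 13 called lists.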

How the results depend on the processing

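The detection share as a covariate, leaving out the arrays of highest and lowest detection share (control replicate 1 and day 30 replicate 3), and raising values under the lowest signal well above background to it were tests chosen after seeing the data, and the other choices were made before the data were examined. The count of genes at an adjusted p under 0.05 was 0 in each comparison and stayed 0 in all other settings except for day 30 against control with slide as a fixed block (1) or a random block (7), and for day 30 against day 10 when 1 array was left out (range 0 to 2, the higher without day 10 replicate 4). The number of called lists moved by more than 1.5 times as follows. With 1 list called, day 10 against control had 3 in the deposited table, 0 with slide as a block and within slide 1, 6 with the detection share as a covariate and 5 without the arrays of highest and lowest share. It was 0 with an estimated correlation and 0 with fry. With 3 lists called, day 30 against control had 1 with normexp, with quantile normalization and with genes above background on all arrays, 6 with the percentile over detected probes and with the median of a gene's probes, 1 with values raised to the lowest signal well above background, and 0 with slide as a block. It was 5 in a fit of only these groups, 13 with the detection share as a covariate, 0 with an estimated correlation and 0 with fry. With 4 lists called, day 30 against day 10 had 2 in the deposited table and with genes above background on all arrays, 0 with slide as a block and within slide 2, 1 with the detection share as a covariate, 0 with an estimated correlation and 0 with fry. The 13 lists were all lower, among them regulatory T cell (median -1.38, adjusted p = 2.72e-08, against up to 0.911 over its alternatives at the preset correlation). Without the covariate, regulatory T cell had an adjusted p of 0.400, or 0.991 with an estimated correlation, which was not run with the covariate. Without 1 array the counts of lists ranged from 1 to 5, 1 to 6 and 2 to 7. The Th17 median at day 10 was 0.23 with the median of a gene's probes, -0.55 with the detection share as a covariate (adjusted p = 0.00542) and -0.68 without the arrays of highest and lowest share (adjusted p = 0.00717). At day 30 it was -0.078 in the deposited table, -0.62 with that covariate (adjusted p = 0.0133) and -0.29 without those arrays. Over the alternatives at the preset correlation the adjusted p of the Th17 list ranged from 0.00542 to 0.987, 0.0133 to 0.997 and 0.0502 to 0.756 (0.951, 0.991 and 0.847 with an estimated correlation). Without 1 array the Th17 median ranged from -0.68 to 0.039 and from -0.086 to 0.62, and for day 30 against day 10 from 0.31 to 0.68. The correlation of the day 10 and day 30 changes was -0.047 with split controls, which share no array, and 0.41 to 0.53 without 1 array. Estimating the correlation within lists, or testing fewer genes or arrays, is itself what ended some of these calls, and for the rest the cause was not tested. The median of all genes shifted by over 0.1 log2 units in the deposited table (-0.10, -0.25 and -0.15). For day 30 against control and against day 10 it shifted with the percentile over detected probes (-0.38 and -0.24), with median centring (0.15 and 0.18), with slide as a block (0.15 and 0.13), with genes above background on all arrays (0.21 and 0.18), and with values raised to the lowest signal well above background (0.12 and 0.14). For day 30 against day 10 it also shifted with normexp (0.11), without the filter on dim probes (0.10) and without day 30 replicate 5 (0.12). Named genes gave 4714 values in other settings, of which 4565 kept their sign and side of the threshold. Of the rest, 144 had another sign and 5 passed the threshold. The changed signs fell in 47 of the 183 gene comparisons, 1 of them with an unadjusted p under 0.05 in the main fit. As no gene was called in the main fits, no called value could have been lost. Signal over background limits the dim genes most: the median 95% interval reached 2.31 log2 units to each side among the dimmest genes (lowest quartile of mean signal) and 1.08 among the brightest (highest quartile).

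With the replicate number as a block (replicate block), 0, 0 and 0 genes passed and 1, 3 and 5 lists were called. It changed no other call than to add macrophage and dendritic cell for day 30 against day 10. Replicate numbers do not pair the arrays: deviations of arrays with the same number had a mean correlation of -0.0047, against 0.00123 for other numbers, with 1 of 15 pairs over 0.1, and 3 of 15 arrays correlated best with their own number.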

Other observations

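The tests of each list's relation to the detection share were chosen only after the results were seen. Markers of other cells showed no common direction. Cytotoxic markers (CD8 T, NK and cytotoxic cell) had medians of -0.03 for day 30 against control (adjusted p = 0.989) and -0.38 for day 30 against day 10, with 12 of 15 genes lower (adjusted p = 0.0945), among them Cd8a at -1.82 (-1.31 with values under background raised to the lowest signal well above it). Macrophage and dendritic cell had medians of -0.16, 0.29 and 0.31 for day 10 against control, day 30 against control and day 30 against day 10 (adjusted p 0.758, 0.530 and 0.0501), with Apoe at 1.52 and Cd74 at 1.53 in the last. Granulocyte and mast cell had 0.03 at day 10 (adjusted p = 0.885) and -0.78 at day 30 (adjusted p = 0.104) against control, the latter -0.04 with values under background raised to the lowest signal well above it (adjusted p = 0.872). In the same order of comparisons, B cell and plasma cell had -0.00, 0.18 and 0.21 (adjusted p 0.885, 0.780 and 0.820), and innate lymphoid cell -0.33, -0.14 and 0.11 (0.885, 0.926 and 0.467). Epithelial lists were not called: absorptive epithelium had -0.02, -0.24 and -0.07 (0.977, 0.780 and 0.729) and secretory and antimicrobial epithelium -0.09, 0.19 and 0.28 (0.885, 0.989 and 0.829). Stroma, muscle and endothelium had -0.21, -0.33 and -0.15 (0.885, 0.771 and 0.799) and pancreatic acinar cell -0.34, -0.12 and 0.10 (0.892, 0.989 and 0.989). The list red blood cell was too dim to be tested. Of its 10 genes, 40%, 34% and 22% were well above background in control, at day 10 and at day 30, beside 63.8%, 58.5% and 51.3% of all spots.

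Genes of cell division lay lower without a call at day 30, except that the median was 0.07 against control and 0.21 against day 10 among genes above background on all arrays. Against control the list was called lower in 5 of its 26 alternatives at the preset correlation (adjusted p from 0.00351 to 0.990 over them; 0.716 with an estimated correlation), among them leaving out control replicate 1 (median -0.66, adjusted p = 0.00351). Proliferation had medians of -0.11, -0.33 and -0.13 in the same order (adjusted p 0.758, 0.104 and 0.409), with 19 of 28 genes below control at day 30, among them the replication gene Mcm6 at -3.78 (SE 1.02; well above background on 2 of 5 day 30 arrays) and the cyclin gene Ccnb2, at least 2.66-fold lower. On average 87.3% of its genes were well above background in control, 81.3% at day 10 and 66.0% at day 30. Over all spots the shares were also lower on the diet, at 63.8%, 58.5% and 51.3%, so the drop is not particular to this list. Immediate early had -0.21 at day 10 (adjusted p = 0.758) and 0.71 at day 30 (adjusted p = 0.0539) against control, and heat shock -0.33 (0.427) and 0.45 (0.573). Cytokine signalling regulators had 0.21, 0.57 and 0.30 (0.660, 0.0539 and 0.409), and TGF-beta signalling -0.21, 0.37 and 0.47 (0.835, 0.699 and 0.138). For day 30 against control, 8 of 26 alternatives at the preset correlation called immediate early, whose median ran from -0.33 to 1.06. Cytokine signalling regulators were called in 6 of 26, with medians from -0.27 to 0.84. Type I interferon response had 0.34, -0.02 and -0.06 (0.885, 0.989 and 0.799), NF-kB targets and inflammatory cytokines -0.05, 0.28 and 0.29 (0.885, 0.771 and 0.409), and microbial pattern sensing -0.13, 0.04 and 0.08 (0.933, 0.989 and 0.965). Apoptosis had -0.09, -0.01 and 0.31 (0.892, 0.989 and 0.968), and unfolded protein and amino acid stress response 0.21, 0.21 and 0.11 (0.892, 0.989 and 0.955).

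Metabolic lists had no call at day 10. Fatty acid oxidation and PPAR targets had medians of 0.06, 0.25 and 0.24 (adjusted p 0.885, 0.989 and 0.829), cholesterol and fatty acid synthesis -0.15, -0.04 and 0.28 (0.892, 0.989 and 0.829), and glycolysis 0.10, 0.02 and 0.17 (0.835, 0.780 and 0.968). Insulin and mTOR signalling had 0.13, 0.04 and -0.08 (0.758, 0.780 and 0.829), and oxidative phosphorylation 0.14 at day 10 (0.758) and 0.41 for day 30 against day 10 (0.0945). Among the T cell lists, Th1 had 0.20 at day 10 (0.920) and 0.21 for day 30 against day 10 (0.799), Th2 -0.41, -0.14 and 0.42 (0.758, 0.989 and 0.474), and regulatory T cell -0.09 at day 10 (0.885) and -0.03 for day 30 against day 10 (0.409). Follicular helper T cell had -0.03, -0.17 and -0.25 (0.885, 0.780 and 0.467), and naive and recirculating T cell 0.33, 0.26 and 0.08 (0.892, 0.989 and 0.799). Gut homing, memory and residency had 0.03, 0.37 and 0.37 (0.885, 0.780 and 0.409), and T cell receptor and CD4 identity 0.12 at day 10 (0.835) and 0.36 for day 30 against day 10 (0.0809).

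Median, mean and test did not always share a sign. At day 10 the mean was -0.17 for Th1, -0.41 for naive and recirculating T cell, -0.19 for gut homing, memory and residency, -0.13 for unfolded protein and amino acid stress response and -0.21 for fatty acid oxidation and PPAR targets, each against a median above 0. It was 0.02 for follicular helper T cell, 0.15 for microbial pattern sensing, 0.25 for innate lymphoid cell and 0.14 for B cell and plasma cell, against a median below 0. At day 30 against control it was -0.20 for naive and recirculating T cell, -0.13 for unfolded protein and amino acid stress response, -0.06 for fatty acid oxidation and PPAR targets, -0.09 for glycolysis, -0.17 for secretory and antimicrobial epithelium and -0.00 for NF-kB targets and inflammatory cytokines. For day 30 against day 10 it was -0.00 for unfolded protein and amino acid stress response, -0.21 for glycolysis, -0.44 for innate lymphoid cell and 0.02 for insulin and mTOR signalling.

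One hypothesis was that many lists follow the share of detected spots, as the ribosomal proteins may (r = -0.895). Over the 34 lists, the within-group Pearson r between the list mean and that share ran from -0.895 to 0.740. After Benjamini-Hochberg adjustment over the 34 permutation p-values 10 lists passed, 9 with a negative and 1 with a positive r. The 9 had mean control signals from 0.67 (TGF-beta signalling) to 5.06 (cytosolic ribosomal proteins), and the 1, microbial pattern sensing, had -1.75. Signals are relative to a percentile of each array. The median of tested genes was -0.51 on control replicate 1 (82.0% of spots) and -1.28 on control replicate 3 (50.9%). The scaling may thus set part of these signs, which was not tested, so r is not independent evidence on each list. Among the 10 lists, heat shock had r = -0.833 and Spearman rho = -0.771 (permutation p 0.00068 and 0.00439), and r = -0.781 without the 2 arrays farthest from the median. T cell receptor and CD4 identity had rho = -0.579 (permutation p = 0.0449) beside its r of -0.878, and r = -0.608 without those arrays. Immediate early had rho = -0.529 (permutation p = 0.0763) and r = -0.568 without them, and oxidative phosphorylation rho = -0.607 (permutation p = 0.0328) and r = -0.452. Within slides 1 and 2, r was -0.942 and -0.854 for heat shock, -0.899 and -0.796 for T cell receptor and CD4 identity, -0.879 and -0.762 for immediate early, and -0.814 and -0.546 for oxidative phosphorylation. The Th17 list had r = -0.564 and rho = -0.471 (permutation p 0.0455 and 0.110; 0.0860 adjusted for r), with r = -0.179 without those arrays but -0.570 and -0.579 within slides 1 and 2.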
